A study of Homo sapiens with 43 samples.

How the data were processed

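Single-cell RNA sequencing libraries from human melanoma were compared across the 3 sites that the sample labels give. There were 21 libraries of cerebrospinal fluid (CSF), the fluid that bathes the brain and its membranes, 14 of brain metastases and 8 from a cutaneous site. Per the labels' protocols, CSF cells were counted and loaded directly. Brain and skin samples were digested enzymatically and sorted for live cells before loading, so the sampled site and the way of preparation change together between CSF and the other sites. All libraries were made on the droplet system of 10x Genomics, in which each droplet tags its RNA with a short barcode sequence, and were sequenced on an Illumina NextSeq 500, per the labels' protocols.

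The submitters' processing notes name Cell Ranger 3.1.0 and the genome build GRCh38. Settings for calling cells and for merging libraries are not given in the sources used here. The authors deposited the merged data as lists, and 3 of them were used: the cell barcodes kept after filtering, the gene features, and the library name that each barcode suffix stands for. The barcode list held 32603 barcodes of 16 bases. Library names were matched to sample titles, and 1 name, with 588 barcodes, had no counterpart among the samples and was left out, which left 32015 barcodes in 43 libraries. Expression values were not analysed here, so no gene is described as higher or lower at any site, no cell type was assigned and doublets were not assessed.

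The outcome computed from these lists was the number of cell barcodes kept per library. A cell barcode is a droplet that the authors' pipeline called as holding a cell, so the number depends on how many cells were loaded, how many survived preparation and how cells were called. Reads and transcripts per barcode were not analysed here, so sequencing depth per cell is unknown. The precision that a library gives is set by its number of barcodes. A cell type with 0 barcodes in a library can still make up to 3 barcodes' worth of it, and this limit, like the exact binomial (Clopper-Pearson) 95% intervals, covers counting error only.

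The library was the unit of replication. Libraries are named by site and by a replicate number given in accession order, which pairs nothing across sites. The labels do not say whether libraries came from separate patients, so p-values measure the spread between these libraries only. Sites were compared in pairs by a two-sided permutation test of the difference in mean log10 barcodes. All assignments were enumerated where a site had fewer than 10 libraries (4292145 for CSF against cutaneous, 319770 for brain against cutaneous), and 100000 resamples were drawn for CSF against brain. Intervals of 95% were obtained by inverting the same test. The spread of libraries was compared by the same test on absolute deviations from the site median, and shares of libraries under 300 barcodes by Fisher's exact test. Each family of 3 comparisons was adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

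Barcode sequences found in more than 1 library served as a check of whether libraries were independent. Droplet barcodes come from a fixed list, so independent libraries share a few by chance. The size of the list was estimated as the sum over all 903 library pairs of the product of their sizes, divided by the number of shared barcodes. Each pair was then tested by a one-sided exact Poisson test, with Benjamini-Hochberg adjustment over the 903 pairs. Expected numbers are given with the list size estimated without the pairs past the threshold. The barcode list of version 2 of the kit holds 737280 sequences, a size within the 95% interval of that estimate. By pairs of sites, the interval between CSF and brain libraries (764486 to 989797) lay above that size, and the other intervals included it. Even use of a single list was therefore not established, and the labels do not name the kit version. On simulated libraries of the same sizes with planted sharing, the pair test recovered 45 of 50 pairs sharing 5% of the smaller library. It recovered 50 of 50 sharing 20% and 50 of 50 sharing 60%, and called 0 of 8880 pairs with nothing planted. Simulated barcodes were drawn evenly from a single list, smaller than the size estimated here. False calls under uneven use of barcodes, or with more sharing within a site, were not simulated. In simulated sets of 14 against 8 libraries, the exact test called 15 of 200 sets without a difference, and 29 of 30 intervals held a true ratio of 3. Both simulated groups had the same spread. In the data the smallest group, cutaneous, had the largest SD of log10 barcodes (0.44, against 0.31 in brain and 0.37 in CSF). The rate of false calls with such unequal spread was not simulated.

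The tests, the 300-barcode threshold, the gene lists and the alternatives, except for 1, were fixed before the data were examined. Alternatives were untransformed numbers, ranks, medians, barcodes found in 1 library only, libraries under 100 barcodes left out, each library left out in turn, other thresholds for small libraries (100, 500 and 1000), other estimates of the list size, and matching on the first 15 bases. Counting pairs of libraries with shared barcodes as 1 library, at the geometric mean of their sizes, was added after seeing the data. The comparison of sharing by site without the pairs past the threshold, and its list sizes by pairs of sites, also came after sharing was tested. Genes are named only as the first 3 reported entries of each fixed list, and 1 entry is not reported here. Libraries named singly are the largest and smallest of each site, those in a pair with excess sharing, and those whose removal changed a call. The brain libraries of equal size, and the others named outside this rule, were chosen after their values were seen. Gene identifiers were matched to GENCODE 44, an annotation of GRCh38, for gene types only. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.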

Results

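The study sampled melanoma at 3 sites to characterise the immune cells around it: CSF, brain metastases and a cutaneous site. Leptomeningeal metastases, which its title names, grow in the membranes around the brain that CSF bathes. The 43 libraries held 32015 cell barcodes, with a median of 475 per library. Brain metastases contributed 19286 barcodes from 14 libraries, CSF 10712 from 21 libraries and cutaneous samples 2017 from 8 libraries. The features listed for these libraries were 33538 genes, of which 33113 matched the GENCODE annotation by identifier. Among these were 19656 protein-coding genes, 12717 long non-coding RNA genes and 409 antigen receptor segments, the gene pieces that B cells and T cells rearrange.

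Genes of the tumour and of the cell types that these sites could hold were represented in the feature list. From the 14 fixed marker lists 73 genes are reported, and each of these was present. The lists were for melanoma cells (MLANA, PMEL and MITF among them), T cells (CD3D, CD3E, CD8A), NK cells (NKG7, GNLY, KLRD1), B cells (MS4A1, CD79A, CD79B) and plasma cells (MZB1, JCHAIN, SDC1). Myeloid lists covered macrophages and monocytes (CD68, CD14, LYZ), microglia (P2RY12, TMEM119, CX3CR1), dendritic cells (CD1C, CLEC9A, LAMP3) and neutrophils (FCGR3B, CSF3R, S100A8). The remaining lists were for fibroblasts (COL1A1, COL1A2, DCN), endothelial cells (PECAM1, VWF, CDH5), oligodendrocytes (MBP, MOG, MOBP), astrocytes (GFAP, AQP4, SLC1A3) and erythrocytes (HBB, HBA1, HBA2). Presence in the list means only that the gene was among those counted, and its expression was not analysed here.

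Brain metastases yielded the most cell barcodes per library. Their geometric mean was 1132 barcodes (mean log10 3.05 ± 0.31, SD, n = 14), against 368 in CSF (2.57 ± 0.37, SD, n = 21) and 169 in cutaneous samples (2.23 ± 0.44, SD, n = 8). Brain libraries ranged from 258 (replicate 13) to 2527 (replicates 10 and 12), CSF libraries from 81 (replicate 7) to 1712 (replicate 4) and cutaneous libraries from 41 (replicate 3) to 707 (replicate 5). A library of at least 1000 barcodes was obtained from 9 of 14 brain metastases, 3 of 21 CSF samples and 0 of 8 cutaneous samples.

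**Figure D1:**
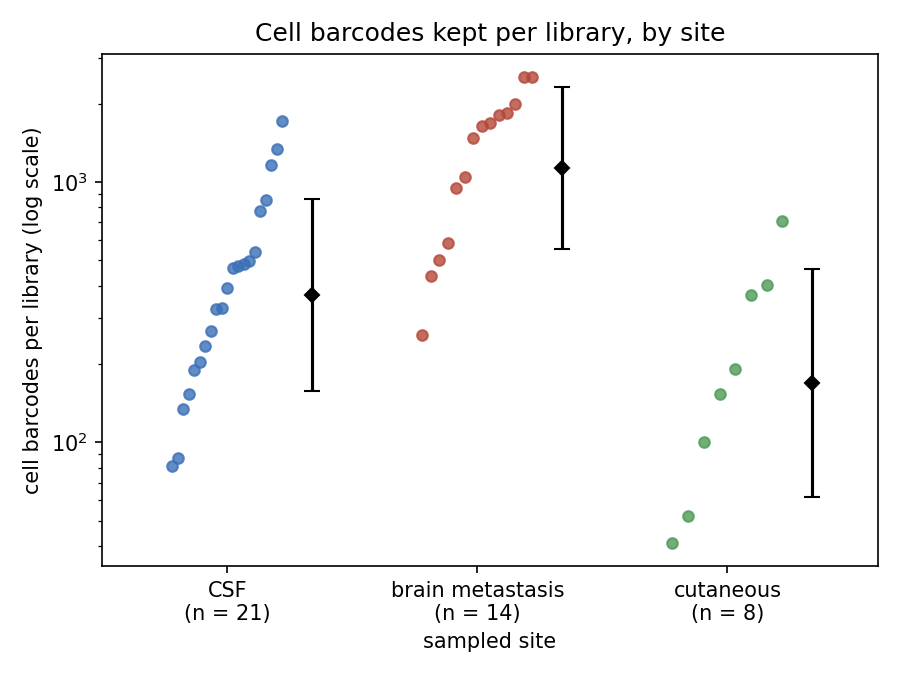
Cell barcodes kept per library on a log scale, by sampled site. Each point is 1 library, and diamonds with bars give the geometric mean and 1 SD of log10 barcodes. All 14 brain libraries lie above the cutaneous median of 173 barcodes.

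Brain and cutaneous samples were both digested and sorted, and they differed the most. Brain libraries held 6.70-fold more barcodes (95% interval 3.11 to 14.5), a difference larger than the spread between libraries (exact permutation test, p = 8.76e-05, adjusted p = 0.000263). All 14 brain libraries exceeded the cutaneous median, and 0 of 8 cutaneous libraries exceeded the brain median of 1560. The difference kept its direction and stayed past the threshold under all 6 alternatives and with each of the 22 libraries left out in turn. Its size ran from 4.35-fold without the libraries under 100 barcodes (cutaneous replicates 3 and 7) to 9.06-fold with medians of log10 barcodes.

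Brain libraries also held more barcodes than CSF libraries, by 3.08-fold (95% interval 1.75 to 5.39; permutation test, p = 0.000350, adjusted p = 0.000525). The brain value exceeded the CSF median of 393 in 13 of 14 libraries, and 1 of 21 CSF libraries exceeded the brain median. This call held under all 6 alternatives and with each of the 35 libraries left out in turn. Brain samples were digested and sorted while CSF was loaded directly, so the site and the preparation cannot be told apart in this comparison.

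CSF libraries held 2.18-fold more barcodes than cutaneous libraries (95% interval 1.02 to 4.66), and 17 of 21 CSF libraries exceeded the cutaneous median. The exact permutation test passed the threshold narrowly (p = 0.0452, adjusted p = 0.0452). The call was lost with ranks, with which the adjusted p of the permutation test was 0.0761, and under 4 of the other 5 alternatives. It was also lost in the exact permutation test on leaving out any of CSF replicates 1, 2, 3, 4, 5, 6, 11, 14, 15, 17 and 20 (ratios from 2.02 to 2.17, adjusted p from 0.0519 to 0.0609). Leaving out any of cutaneous replicates 2, 3, 4, 7 and 8 did the same, with ratios from 1.78 to 2.22 and adjusted p from 0.0549 to 0.136 in that exact test. Without cutaneous replicate 3, the smallest library, the ratio was 1.78.

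Small libraries were most frequent among cutaneous samples. Under 300 barcodes were kept in 5 of 8 cutaneous libraries (62.5%), 8 of 21 CSF libraries (38.1%) and 1 of 14 brain libraries (7.14%). The share differed between brain and cutaneous libraries (Fisher's exact test, two-sided, p = 0.0109, adjusted p = 0.0326). It did not pass the threshold between CSF and brain (Fisher's exact test, adjusted p = 0.0835) or between CSF and cutaneous libraries (Fisher's exact test, adjusted p = 0.406). With thresholds of 500 and 1000 barcodes the CSF and brain libraries did differ, and with 100 the brain and cutaneous libraries did not. All these tests counted every library as separate, although cutaneous replicates 1 and 2, and 3 and 8, shared more barcodes than chance. The tests were not rerun with such pairs counted as 1 library, so the brain and cutaneous call may depend on them.

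These sizes set what the absence of a cell type from a single library can show. A cell type with 0 barcodes could make up to 0.193% of the median brain library, 0.763% of the median CSF library and 1.76% of the median cutaneous library, the medians being taken over each site's limits. The limit ranged from 0.119% to 1.16% in brain, from 0.175% to 3.70% in CSF and from 0.424% to 7.32% in cutaneous libraries.

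The variability of yield from library to library was not found to differ between sites. The mean absolute deviation of log10 barcodes from the site median was 0.24 in brain, 0.29 in CSF and 0.35 in cutaneous libraries. None of the 3 pairwise differences passed the threshold (two-sided permutation tests, exact where cutaneous libraries entered, adjusted p = 0.541 for each). The unadjusted p was 0.312 for brain against cutaneous, the lowest of these permutation tests.

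Pooled over cells, the data set was weighted towards the brain. Brain metastases supplied 60.2% of all barcodes (exact 95% interval 59.7 to 60.8), CSF 33.5% (32.9 to 33.98) and cutaneous samples 6.30% (6.04 to 6.57). These intervals cover counting error only and not the spread between libraries. Leaving out the largest library of each site moved brain to 61.9% and cutaneous samples to 4.84%, outside their intervals, while CSF stayed within its own at 33.2%. Within the cutaneous samples, 3 of 8 libraries held 73.3% of the barcodes and replicate 5 alone held 35.1%. The largest library held 15.98% of CSF barcodes and 13.1% of brain barcodes. Weighted by size, the cutaneous libraries counted as 4.66 equal libraries (the inverse Simpson index), the CSF libraries as 12.4 and the brain libraries as 10.9.

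Barcode sequences were compared between libraries to check that the libraries were separate. Of 31201 different sequences, 30401 occurred in 1 library, 786 in 2 and 14 in 3. The 898 pairs that did not pass the threshold shared 644 barcodes, from which the list size was estimated as 761246 sequences (95% Poisson interval 704658 to 823639). In all 43 libraries the number shared with the others, leaving out the pairs past the threshold, had a Poisson interval that included the number expected from that size. The size was estimated from these same pairs, so this result was partly built in and does not show that the libraries are independent. Without the pairs past the threshold, libraries of the same site shared 1.24 times as often as others (permutation of site labels, p = 0.00685). Pairs within brain (251 shared barcodes) and between CSF and brain (238) weighed most in this ratio, and pairs within cutaneous libraries held 3. Whether the higher rate holds at each site was not tested.

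Past the threshold were 5 of the 903 library pairs. Cutaneous replicates 1 and 2 shared 131 barcodes where 0.102 were expected, which was 68.2% of the smaller library (exact 95% interval 61.1 to 74.7) and 32.4% of the larger. CSF replicates 12 and 18 shared 44 where 0.0824 were expected, or 18.7% of the smaller library (13.9 to 24.3) and 16.5% of the larger. The other 3 pairs linked CSF replicate 9, cutaneous replicate 3 and cutaneous replicate 8, which shared 5 sequences in all, 2 of them present in all 3 libraries. The adjusted p of these 3 pairs was at most 0.00431 in the exact Poisson test. Pairs within a site (cutaneous 1 with 2 and 3 with 8, CSF 12 with 18) were also counted as 1 library each, which left 20 CSF and 6 cutaneous libraries. Each such pair was given the geometric mean of its 2 library sizes. Pooled, the pairs held 465, 139 and 458 different barcodes, and ratios with these sizes were not computed. With the geometric means, brain libraries held 6.20-fold more barcodes than cutaneous libraries (95% interval 2.70 to 14.3), and CSF libraries 2.05-fold more (0.866 to 4.88, exact permutation test, adjusted p = 0.0982).

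**Figure D2:**
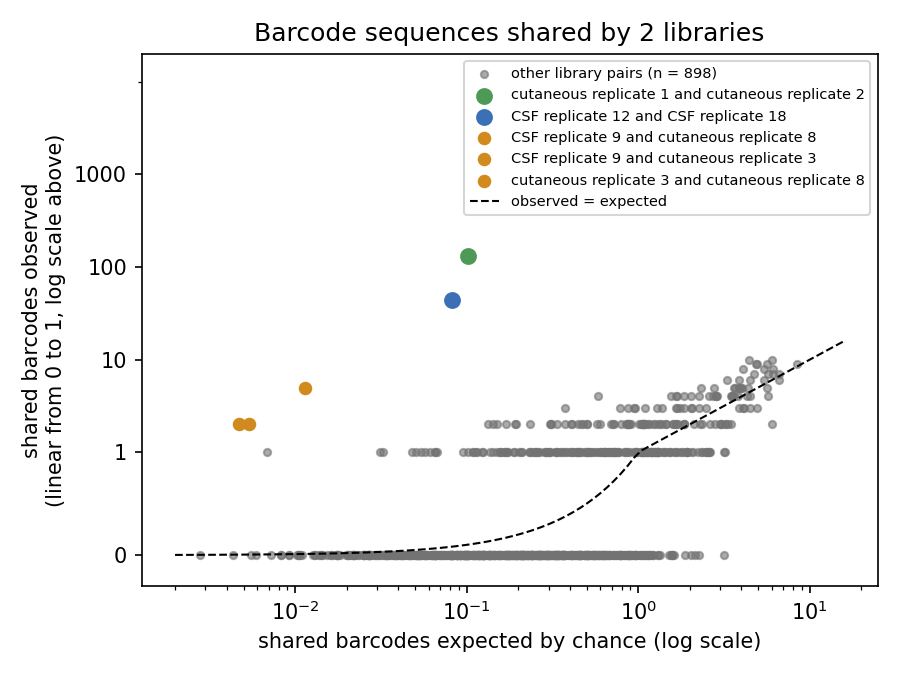
Barcode sequences shared by each pair of libraries against the number expected by chance, for 903 pairs (x axis on a log scale, y axis linear from 0 to 1 and log above). Coloured points are the 5 pairs past the threshold, 2 of them with 131 and 44 shared barcodes and 3, from 3 small libraries, with 2 to 5, and the dashed line marks equality. No other pair shared more than 10.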

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

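The exact Poisson tests of library pairs were set before the data were examined, and the other tests of explanations in this part were chosen after the result was seen. The results listed here are library pairs with more barcode sequences in common than chance gives, a signal in the barcode sequences themselves rather than in their number.

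Cutaneous replicates 1 and 2 shared 131 barcodes, and CSF replicates 12 and 18 shared 44. Chance draws from one list with every barcode equally likely give 0.102 and 0.0824, so such draws are excluded for both. A single library deposited under both names would put nearly all barcodes of the smaller library in the larger, and 68.2% (61.1 to 74.7) and 18.7% (13.9 to 24.3) were found there. Both pairs are neighbours in the merged list. The other 40 neighbouring pairs shared 1.27 times the expected number (95% Poisson interval 0.958 to 1.65). This argues against a cross-over between all neighbours as large as in these 2 pairs. A smaller cross-over cannot be told from none, given that interval and an expected number not matched for site. Barcoded material or reads of one library in the other, such as reads assigned to the wrong library, may account for the pairs. This stays open, because 32.4% and 16.5% of the larger libraries are shared and reads per barcode were not analysed here. Each droplet tags its own RNA, so cells mixed before separate loading would not by themselves give shared sequences. No biological explanation was tested.

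CSF replicate 9 and cutaneous replicate 8 shared 5 barcodes, CSF replicate 9 and cutaneous replicate 3 shared 2, and cutaneous replicates 3 and 8 shared 2. These are libraries of 87, 100 and 41 barcodes, and 2 sequences occurred in all 3. Chance draws with every barcode equally likely are excluded by the exact Poisson tests (highest adjusted p = 0.00431), but uneven use of barcodes is not. The pairs that shared 2 barcodes rest on the same 2 sequences, so they are not separate evidence. A candidate explanation is that the same sequences recur wherever few cells were called. The 87 further pairs of libraries under 300 barcodes shared 3 barcodes where 2.66 were expected. The pair of CSF replicates 12 and 18, with its own excess of 44, was left out of these. The ratio of 1.13 has an interval of 0.232 to 3.29, which is too wide to decide. The libraries come from 2 sites, and no biological explanation was tested.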

How the results depend on the processing

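The excess of brain over CSF and over cutaneous libraries kept its direction and its side of the threshold under every alternative run, but brain over cutaneous moved from 6.70 to 4.35 without libraries under 100 barcodes. CSF against cutaneous lost its call with untransformed numbers (ratio of means 2.02), ranks (CSF higher in 71.7% of library pairs, with ties counted as 0.5), medians of log10 barcodes (ratio 2.29 after back-transformation), libraries under 100 barcodes left out (ratio 1.65) and, an alternative chosen after seeing the data, pairs sharing barcodes counted as 1 library (ratio 2.05). The adjusted p of these 5 exact permutation tests ran from 0.0700 to 0.153. The call held with barcodes found in 1 library only (ratio 2.63, exact permutation test, adjusted p = 0.0170). That alternative removed the barcodes that cutaneous replicates 1 and 2 shared from both, leaving 260 of 404 and 58 of 192. This lowered the cutaneous mean, so the larger ratio follows in part from the sharing. With 1 library left out the call was lost in 16 of 29 cases, the ratio running from 1.78 to 2.67. Of small-library shares, CSF exceeded brain by 57.1 percentage points at 500 barcodes and 50 at 1000, both now past the threshold, and brain against cutaneous was -25 points at 100 barcodes, no longer past it. Leaving out the largest library of each site gave brain 61.9% and cutaneous 4.84% of all barcodes, and barcodes found in 1 library only gave 60.9% and 5.51%. No difference in spread passed the threshold under any alternative, and the count of 5 pairs with excess sharing stayed within 1.5 times under each. Library size limits what the absence of a cell type in a single library can show.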

Other observations

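The share of brain barcodes found elsewhere, as a test of cross-over, was chosen after the result was seen. So was the comparison of brain replicates 10 and 12. Leaving out the pairs past the threshold, in the comparison of sharing by site and in its list sizes by pairs of sites, also depended on the sharing seen. The other comparisons in this part, among them sharing by site over all pairs, were set before the data were examined.

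The brain libraries stood above the cutaneous libraries although both were digested and sorted. The ratio was 6.70 (3.11 to 14.5). Barcodes of other libraries that crossed over into the brain libraries would have to make up 85.1% of the brain barcodes to give this ratio alone. Cross-over that left each barcode in both libraries would show as sharing of about that size. Of the brain barcodes, 4.01% (exact 95% interval 3.74 to 4.29) were also kept in another library. Each brain library shared about the number expected by chance (ratios from 0.750 to 1.18), so the 4.01% does not measure cross-over. It lies far under 85.1%, which argues against cross-over of that kind as the whole of the excess. Cross-over of barcodes that were not kept in their library of origin would leave no sharing and cannot be judged here. The number of cells loaded, the size of the tissue piece, details of digestion and sorting, cell survival and the biology of the sites may each contribute and stay open, as untested. For CSF against brain, preparation and site remain confounded.

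Libraries of the same site shared barcodes 1.24 times as often as libraries of different sites, after leaving out the 5 pairs with an excess (permutation of site labels over libraries, p = 0.00685), and 1.87 times as often with all pairs (permutation p = 0.0232). By pairs of sites, the list size behind the sharing was 673167 within brain (95% Poisson interval 594843 to 764872), 711842 within CSF (567021 to 906557) and 505372 within cutaneous libraries (172929 to 2450600). It was 868032 between CSF and brain (764486 to 989797), 997432 between brain and cutaneous libraries (729633 to 1402670) and 553688 between CSF and cutaneous libraries (405029 to 778639). A smaller size means more sharing, and differences between single pairs of sites were not tested. The size between CSF and cutaneous libraries was smaller than within brain or within CSF, so the estimates did not all follow the site.

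Brain replicates 10 and 12, the largest libraries, each held 2527 barcodes. They shared 9 sequences where 8.39 were expected by chance, so they are not copies of each other.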
